A study of Mus musculus with 19 samples.

How the data were processed

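RNA was measured in 19 livers of mice that carried a Cre-dependent channelrhodopsin-2 gene at the ROSA26 locus. Mice labelled tg also carried a Cre driver in the gene of agouti-related peptide (AgRP), so that blue light could excite their AgRP neurons, and mice labelled wt lacked the driver. All mice received 473 nm light above the arcuate nucleus in pulses of 10 ms at 20 Hz, 3 s on and 1 s off, without food, for 2 h or 4 h, and livers were taken at zeitgeber time 7.5, per the labels' protocols. The labels name mice of 4 groups, with 5 wt and 4 tg mice at 2 h and 5 of each at 4 h.

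Poly-A selected, stranded libraries were made from 1 µg of RNA, and every RNA integrity number was above 8, per the labels' protocols. The submitters' processing notes name STAR, Salmon 1.4.0, DESeq2 1.30.0 and the mouse build GRCm38.p6, without saying what each did. The authors deposited whole-number counts per gene in 1 table of 14576 genes. Of these, 257 genes had no value in any 4 h library, and their highest mean count at 2 h was 5.11, so they were left out and 14319 genes stayed. The authors also deposited 1 table per duration with log2 fold changes, p-values and adjusted p-values from their own comparison of tg with wt. Means of normalised counts in those tables could be recomputed from the counts of each duration alone, so the authors treated the durations separately. Their 4 h table holds 206 genes without a row of counts. Symbols came from the authors' tables, and positions from the GENCODE M21 annotation of build GRCm38, where all 12493 fitted genes were found. How transcript estimates became whole counts is not given in the sources used here, so genes with near-identical copies carry an uncertainty that was not measured.

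Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by edgeR's expression filter with a minimum count of 10 and a minimum total of 15, which left 12493. Libraries were scaled by TMM. A model with 1 mean per group was fitted to all 19 libraries, with robust dispersion estimates, and contrasts were tested with edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment at 0.05. The contrasts tested were tg against wt at 2 h, at 4 h and on average, the difference between those effects, and 4 h against 2 h within each genotype. Standard errors of log2 fold changes were derived from the fold change and the test statistic. The biological coefficient of variation was 0.183, with 15 residual degrees of freedom. CPM values were computed with TMM-scaled library sizes.

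In total 43 gene lists were fixed before the data were examined, and the 40 with at least 5 measured members were tested with camera of limma 3.58.1 on voom values with a preset correlation of 0.01. Calls were set beside camera with an estimated correlation and beside fry, which tests whether a list's genes move on balance in 1 direction and makes no comparison with other genes. Adjustment was over the tested lists of each contrast. The rule for named genes, fixed at the same time, took the 8 largest rises and 8 largest falls of each genotype contrast among called genes with a mean of at least 1 CPM, up to 4 called members of each list or 1 member of a list without calls, the 5 largest rises and falls for the other contrasts, and the 4 smallest p-values where nothing was called. The text names a part of these genes, and some are not reported here. List medians were recomputed under each scaling, a check added after seeing the data, and no list called by camera changed sign. The camera calls were also recomputed without each library in turn, again a check added after seeing the data.

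Total counts per library ran from 21474255 to 32721828. On simulated data with the same means, totals and dispersions, the test at 2 h over 12398 genes recovered 46.3% of genes changed 1.5-fold, 83.6% of those changed 2-fold and 93.9% of those changed 4-fold, and 3.25% of its calls were false. For the 4 h contrast these shares were 50.7%, 77.6% and 93.9%, with 3.90% false. Simulated genes were drawn independently of each other. The real libraries also vary in ways shared by many genes, so these shares need not hold for them. No pair of libraries of the same group agreed within sampling noise, the lowest chi-square per degree of freedom over 36 pairs being 21.2. Pairs from different groups were not checked in this way. Alternatives were other scalings, other filters, DESeq2 1.42.0, limma-voom with and without sample weights, blocks for the numbers in sample names, fits to 2 groups, and fits without each library in turn. Transcript length was the longest annotated transcript of a gene. Plots were made with matplotlib 3.10.9.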

Results

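Liver RNA was sequenced in mice whose AgRP neurons, hypothalamic neurons that drive hunger, could be excited by light, and in mice without the Cre driver under the same light. The 4 groups were wt 2 h (5 mice), tg 2 h (4 mice), wt 4 h (5 mice) and tg 4 h (5 mice). Total counts per library were 22962054 to 32721828 in wt 2 h, 22557006 to 25366961 in tg 2 h, 22263155 to 30941927 in wt 4 h and 21474255 to 28419872 in tg 4 h. The first principal component held 24.7% of the variance and placed tg libraries between -32.5 and -5.23 and wt libraries between -4.90 and 35.9. AgRP itself was not analysed here, so the genotype labels had no direct check.

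The comparison at 2 h asked which liver transcripts differed between tg and wt mice after 2 h of light. As no tg mice went without light, effects of excitation cannot be told apart from those of carrying the Cre driver, at either duration. Cdkn1a, a cell cycle inhibitor, rose from 1.12 ± 0.461 CPM (SD, n = 5) in wt to 13.3 ± 6.36 CPM (SD, n = 4) in tg, a log2 change of 3.59 ± 0.60 (SE). The gene (ENSMUSG00000023067) spans positions 29090976 to 29100727 of chromosome 17 in build GRCm38. Ddit4, an inhibitor of mTORC1 signalling, rose by 3.14 ± 0.54 from 6.26 ± 5.65 to 55.0 ± 5.24 CPM, or by 3.88 without wt 2 h replicate 2. Slc38a2, an amino acid transporter, rose by 2.24 ± 0.24 from 104 ± 20.3 to 492 ± 51.9 CPM. Arrdc3, an arrestin-domain protein, changed by -3.38 ± 0.63, from 169 ± 60.3 to 16.1 ± 4.06 CPM. Other large rises were those of Jaml (2.96 ± 0.43), Tmem100 (2.62 ± 0.49) and Gadd45b (2.56 ± 0.47), and other large falls those of Tfap4 (-1.90 ± 0.27), Efna1 (-1.85 ± 0.35), Gadd45a (-1.75 ± 0.30) and Tbx3 (-1.67 ± 0.26). Of 12493 genes, 270 changed, 142 higher and 128 lower, by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and 1460 had an unadjusted p under 0.05. Single libraries moved this count by over 1.5 times, to 165 without tg 2 h replicate 1, 177 without replicate 2, 151 without replicate 5 and 161 without wt 2 h replicate 5. Among the largest rises the call of Gadd45g (3.16 ± 0.78) ended without any 1 of the 9 libraries, with adjusted p of 0.0671 to 0.109 in those fits by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. By the same test with Benjamini-Hochberg adjustment in edgeR, Fam107a (4.14 ± 1.00) kept its call only without tg 2 h replicate 3 or wt 2 h replicate 4, and Mt2 (2.67 ± 0.64) lost it without tg 2 h replicate 1 or 5 or wt 2 h replicate 3, 4 or 5, with adjusted p of up to 0.114 and 0.130. The change of Fam107a was 5.01 without wt 2 h replicate 4.

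Glucocorticoid receptor targets rose as a group at 2 h. Of 27 measured members 15 rose and 0 fell, or 22 when adjusted over the list alone, with a median log2 change of 1.58. Tat, which begins tyrosine breakdown, rose by 1.99 ± 0.30 from 918 ± 312 to 3650 ± 352 CPM, and Sds, a serine dehydratase, rose by 1.22 ± 0.21. The list was shifted by camera, and it stayed so with an adjusted p = 0.0131 with an estimated correlation. Gluconeogenic and cAMP-responsive genes were the other list that held, with an adjusted p = 0.0130 with an estimated correlation, and both lists held in each of the 9 fits that left out 1 library. Of the 15 measured gluconeogenic and cAMP-responsive genes 3 rose and 0 fell, or 7 adjusted over the list alone. Tat, 1 of the 3, is also in the glucocorticoid list, so the lists are not separate. Without shared members the list kept 13 genes and its call (adjusted p = 0.000267 by camera with the preset correlation). An estimated correlation was not tried on these 13. Ppargc1a, a coactivator of fasting genes, rose by 1.69 ± 0.23 from 9.94 ± 1.90 to 32.1 ± 12.2 CPM, while Pck1, which encodes a rate-limiting enzyme of gluconeogenesis, rose by 0.82 ± 0.19. The call of Pck1 ended without tg 2 h replicate 1, 2 or 5 or wt 2 h replicate 1 or 5, with adjusted p from 0.00831 to 0.0714 over all fits that left out 1 library by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

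Other lists were called by camera at 2 h with the preset correlation and not with an estimated one. Of 23 urea cycle and amino acid breakdown genes 4 rose, or 7 adjusted over the list alone, including Slc25a15, the mitochondrial ornithine carrier, at 1.06 ± 0.18, and the list had an adjusted p = 0.363 with an estimated correlation and an adjusted p = 0.0458 by fry. Among 20 immediate early genes 4 rose and 1 fell, or 7 and 1 adjusted over the list alone, with Jun at 2.12 ± 0.41, Zfp36 at 1.26 ± 0.20 and Btg2 at 1.25 ± 0.26, and the list had an adjusted p = 0.650 with an estimated correlation. Xenobiotic genes rose in 3 of 21 cases, or 4 adjusted over the list alone, among them Alas1, the first enzyme of heme synthesis, at 1.66 ± 0.32, with a list adjusted p = 0.479 with an estimated correlation. Genes of endoplasmic reticulum chaperones and of the unfolded protein response, tested as a joint list, rose in 2 of 27 cases, or 5 adjusted over the list alone. The 2 were Herpud1, at 0.97 ± 0.20, and Ppp1r15a, and the list had an adjusted p = 0.479 by camera with an estimated correlation. Interferon-stimulated genes were the 1 list shifted down, in which Irf1, an interferon-induced transcription factor, fell by 1.23 on the log2 scale and no other of 18 members was called, with an adjusted p = 0.754 with an estimated correlation. The remaining lists called with the preset correlation were acute phase genes (2 of 25 rose, adjusted p = 0.975 with an estimated correlation), PPARalpha targets (2 of 34 rose, adjusted p = 0.938 with an estimated correlation), glycogen and glycolysis genes (1 of 18 rose, adjusted p = 0.744 with an estimated correlation) and periportal markers (2 of 10 rose, adjusted p = 0.650 with an estimated correlation). The acute phase call turned downward without tg 2 h replicate 1 (adjusted p = 0.728 by camera with the preset correlation) and also ended without wt 2 h replicate 1, 4 or 5. The mean log2 CPM of its members, relative to all libraries, was 1.44 in tg 2 h replicate 1 and -0.532 to -0.108 in the other tg 2 h libraries. In the same library mitochondrially encoded transcripts held 7.75% of counts, against 10.0% to 12.9% in the other 2 h libraries. By the same test the PPARalpha call ended without tg 2 h replicate 1 or wt 2 h replicate 3 (adjusted p up to 0.220), and the glycogen call without tg 2 h replicate 2 or 3 or wt 2 h replicate 3 (up to 0.207). The periportal call ended without tg 2 h replicate 2, 3 or 5 or wt 2 h replicate 1 or 2 (up to 0.235), and the xenobiotic call without tg 2 h replicate 2 (0.0899). With glucocorticoid receptor targets taken out of the other lists, the acute phase (adjusted p = 0.343 by camera with the preset correlation), periportal (0.282) and PPARalpha (0.0620) calls ended.

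Autophagy genes, the subject of the series title, showed no call at 2 h. None of 45 core autophagy genes passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, over all genes or adjusted over the list alone, and the list had a median of 0.02, a mean of -0.01 and an adjusted p = 0.886 by camera in the downward direction. Under upper-quartile scaling the median of this list was -0.005 at 2 h and -0.015 at 4 h. Of 37 lysosome genes Atp6v0d1, a subunit of the proton pump, rose by 0.48 ± 0.09 and Flcn, a regulator of mTORC1 and TFEB, was lower by a log2 change of -0.59 ± 0.14, a call that ended without any 1 of the tg 2 h libraries or wt 2 h replicate 3 or 5. In 19 clock genes 2 rose and 2 fell. Ciart, a clock repressor, rose by 1.20 ± 0.23, and Nr1d1, a repressor of Arntl, changed by -1.64 ± 0.38 from 79.2 ± 25.3 to 25.4 ± 13.2 CPM, a call that ended without any 1 library except tg 2 h replicate 5 and wt 2 h replicate 2. The clock list had a median of -0.03 and a mean of -0.05 but an upward camera direction (adjusted p = 0.886). Markers of macrophages, neutrophils, T and NK cells, B cells, sinusoidal endothelium, stellate cells, erythroid cells and, as a joint list, adipocytes and mesothelium were not shifted by camera at either duration.

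At 4 h the same question was asked after longer light. Cdkn1a rose by 5.06 ± 0.58 from 1.55 ± 1.06 CPM in wt (SD, n = 5) to 52.7 ± 27.4 CPM in tg (SD, n = 5), and Fam107a, an actin-associated stress-response gene, rose by 4.87 ± 0.89 from 1.16 ± 1.43 to 35.8 ± 18.2 CPM, or by 5.56 without wt 4 h replicate 5. Ddit4 rose by 3.65 ± 0.53 and Gadd45b by 3.17 ± 0.45. Rnf152, a lysosomal ubiquitin ligase that restrains mTORC1, changed by -1.74 ± 0.18 from 42.7 ± 6.33 to 12.8 ± 1.69 CPM, and Klhdc7a by -1.92 ± 0.25. Tgm1 (-2.13 ± 0.39) and Nrep (-2.18 ± 0.46) also fell. In all 1423 genes changed, 718 higher and 705 lower, by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and 177 of the rises and 103 of the falls exceeded 2-fold. The count was 895 without wt 4 h replicate 3. Arrdc3 was lower by a log2 change of -1.74 ± 0.53, or -2.69 without tg 4 h replicate 3, and its call ended without any 1 library except tg 4 h replicate 3 and wt 4 h replicate 5, with adjusted p from 0.000422 to 0.103 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

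Of 27 glucocorticoid receptor targets 22 rose and 0 fell at 4 h, or 23 adjusted over the list alone, with a median of 1.54 and an adjusted p = 0.0427 with an estimated correlation. Tat rose by 2.35 ± 0.30 and Sds by 1.76 ± 0.21, the latter from 254 ± 59.7 to 860 ± 120 CPM. Gluconeogenic and cAMP-responsive genes rose in 6 and fell in 1 of 15 cases, or 7 and 1 adjusted over the list alone, again with an adjusted p = 0.0427 with an estimated correlation, and Ppargc1a (1.63 ± 0.22) and Pck1 (0.89 ± 0.18) were among them. With an estimated correlation both calls ended without tg 4 h replicate 2 or 4 or wt 4 h replicate 1, 4 or 5, and 1 of them each without tg 4 h replicate 1 (glucocorticoid targets) or 3 (gluconeogenic genes), with adjusted p of up to 0.0842 and 0.105, whereas with the preset correlation both were called in all 10 fits. Urea cycle and amino acid breakdown genes rose in 14 of 23 cases, or 16 adjusted over the list alone, including Aass, the first enzyme of lysine breakdown (1.24 ± 0.18), Slc38a2 (1.85 ± 0.23) and Slc25a15 (1.16 ± 0.18), with a list adjusted p = 0.187 with an estimated correlation. Insulin-repressed FoxO targets rose in 7 of 17 cases, or 8 adjusted over the list alone, with Igfbp1, which binds insulin-like growth factors, at 2.66 ± 0.55 (3.68 without wt 4 h replicate 1) and Klf15, a fasting transcription factor, at 0.50 ± 0.12, and an adjusted p = 0.370 with an estimated correlation. Immediate early genes rose in 6 and fell in 1 of 20 cases (adjusted p = 0.937 with an estimated correlation), and periportal markers rose in 4 of 10 (adjusted p = 0.382 with an estimated correlation). The 47 ribosomal protein genes were shifted down by camera with a median of -0.10 and 0 members called, and an adjusted p = 0.937 with an estimated correlation. Across genes, which are not independent replicates, longer transcripts had higher fold changes at 4 h (Spearman's rho 0.196) and less so at 2 h (0.0607). The ribosomal call ended without tg 4 h replicate 1 or 5 or wt 4 h replicate 2 or 3 (adjusted p up to 0.237 by camera with the preset correlation), and that of immediate early genes without wt 4 h replicate 5 (0.142). With glucocorticoid receptor targets taken out of the other lists, the FoxO and periportal calls ended (each with an adjusted p of 0.0708 by camera with the preset correlation).

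Core autophagy genes went both ways at 4 h. Of 45 members 4 rose and 3 fell, or 4 and 5 adjusted over the list alone, with a median of 0.02 and an adjusted p = 0.853 by camera. Ulk1, the kinase that starts autophagy, rose by 0.50 ± 0.10 from 105 ± 9.31 to 149 ± 16.0 CPM, while Atg101, a partner in the same kinase complex, changed by -0.48 ± 0.10 and Atg14, a subunit of the autophagy lipid kinase, by -0.45 ± 0.11. Clock genes rose in 7 and fell in 5 of 19 cases, with a median of 0.09 and a mean of -0.04. Nr1d1 changed by -1.75 ± 0.35, Bhlhe41 by -2.31 ± 0.39, Dbp, a clock output factor, by -1.16 ± 0.18 and Per3 by -1.28 ± 0.26, while Ciart rose by 1.21 ± 0.22 and Arntl, an activator of the core clock loop, by 1.29 ± 0.32. Plin5, a lipid droplet coat protein, rose by 2.41 ± 0.31, among 5 of 34 PPARalpha targets that rose. Lgr5, a marker of pericentral hepatocytes, changed by -1.39 ± 0.19 from 4.89 ± 0.320 to 1.87 ± 0.365 CPM. Of 13 NF-kB genes 2 rose and 1 fell, and Vcam1, an adhesion molecule, was among those that rose, at 1.32 ± 0.24. The fall was that of Il1b (-1.90), whose call ended without wt 4 h replicate 3 (-1.23, adjusted p = 0.151 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment).

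**Figure D1:**
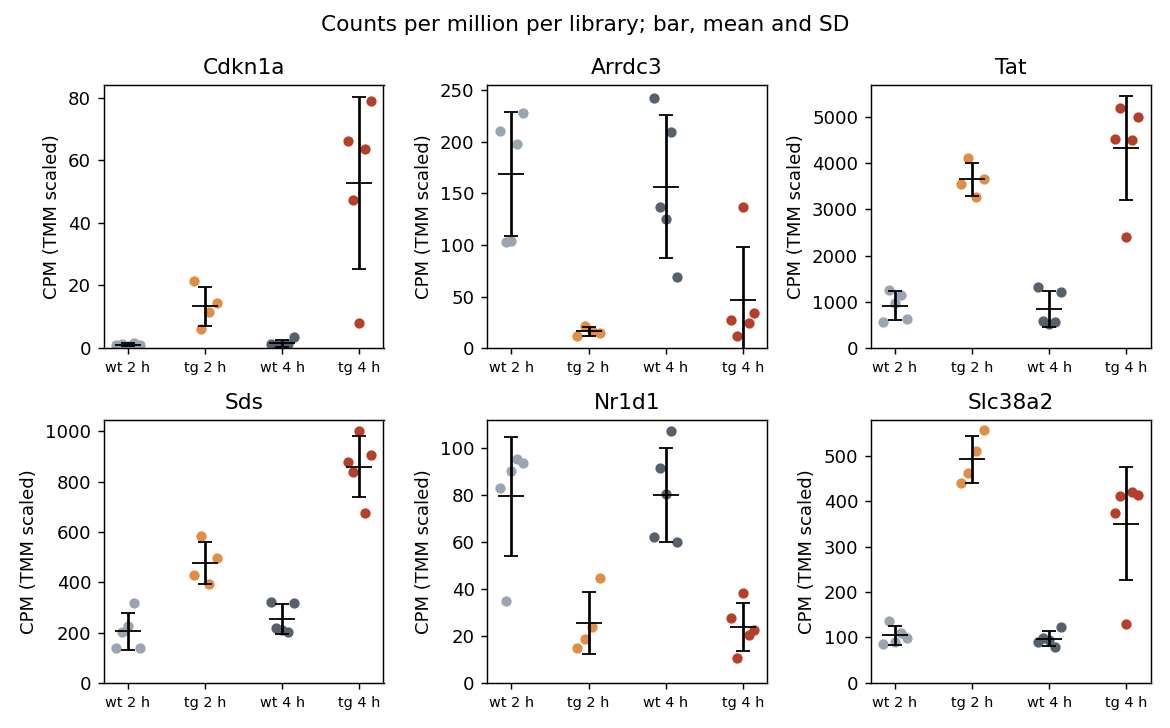
CPM of 6 genes in each library by group, with the mean and SD as bars (cut off at 0). Cdkn1a averaged 52.7 CPM in tg 4 h mice and 1.55 CPM in wt 4 h mice, and 1 tg 4 h library lay nearer to wt in Cdkn1a, Arrdc3, Tat and Slc38a2.

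**Figure D2:**
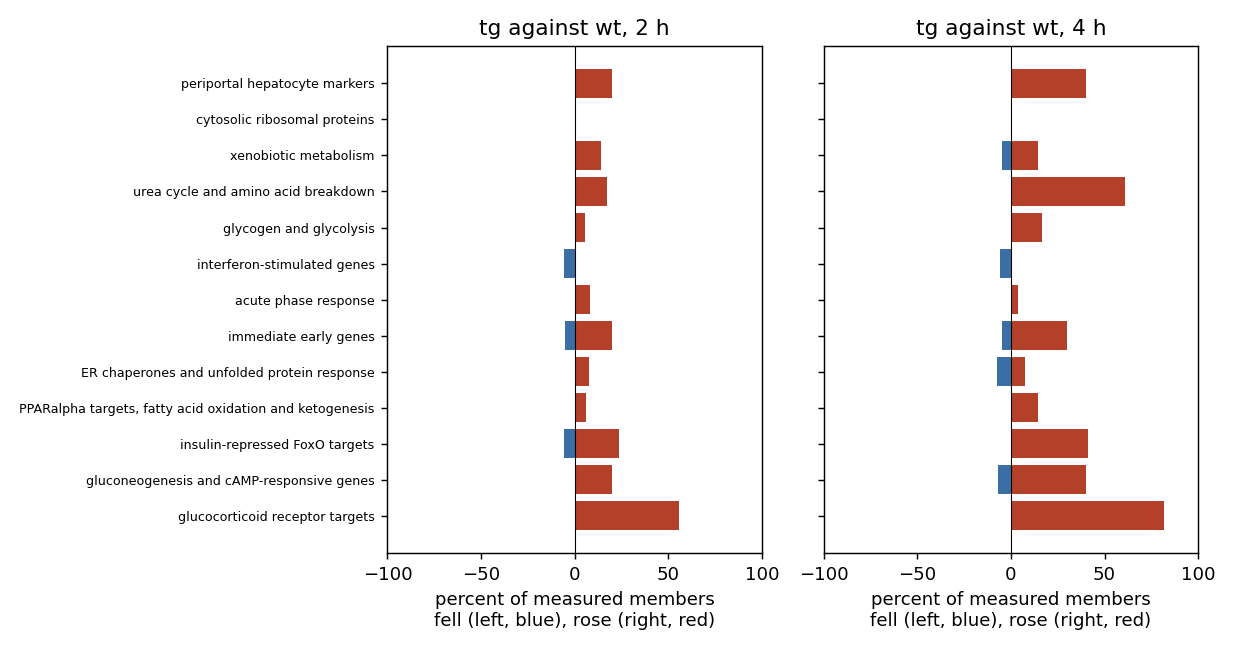
Percent of measured members of each gene list that rose (red, right) or fell (blue, left) at 2 h and 4 h, for lists called by camera at either duration with the preset correlation. Glucocorticoid receptor targets had the largest share that rose among these lists, 15 of 27 at 2 h and 22 of 27 at 4 h.

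One tg 4 h library stood apart. Between the mean of the wt libraries (0) and that of the other tg libraries (1), tg 4 h replicate 3 had a median position of 0.554 over the 1460 genes called without it, against 0.905 to 1.10 for the other tg 4 h libraries. Among wt libraries replicate 1 lay at 0.534 and the others between -0.160 and 0.268. In wt 4 h replicate 1 mitochondrially encoded transcripts held 7.83% of counts, against 10.6% to 12.6% in the other wt 4 h libraries, and it had the highest score, 34.0, on the leading axis of variation within groups. For called glucocorticoid receptor targets the position of tg 4 h replicate 3 was 0.257 (wt libraries -0.111 to 0.221), and for called urea cycle and amino acid breakdown genes 1.46 (wt libraries -0.179 to 0.406). Its Cdkn1a, Fam107a and Arrdc3 levels are part of the SDs given for the 4 h group.

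**Figure D3:**
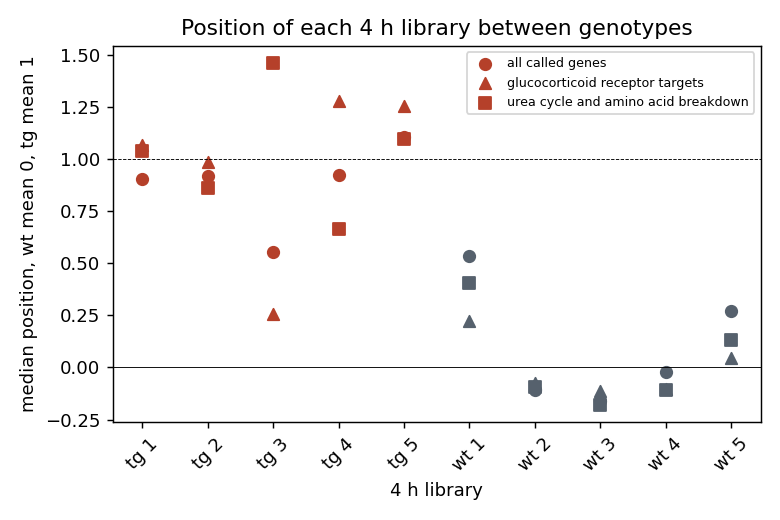
Median position of each 4 h library between wt (0) and tg (1) over genes called without it, for all called genes (circles), glucocorticoid receptor targets (triangles) and urea cycle and amino acid breakdown genes (squares). The tg replicate 3 circle lies at 0.554 and the wt replicate 1 circle at 0.534.

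The genotype effects at 2 h and 4 h shared direction. Of 142 genes higher at 2 h 126 were also higher at 4 h (8.16 expected for independent lists), and of 128 lower genes 78 were also lower (7.22 expected), with 0 in opposite directions. The comparisons used different mice in both genotypes. Across 12493 genes, which are not independent replicates, Pearson's r was 0.616 and Spearman's rho 0.507. The mean effect over both durations changed 1774 genes, 872 higher and 902 lower, by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

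**Figure D4:**
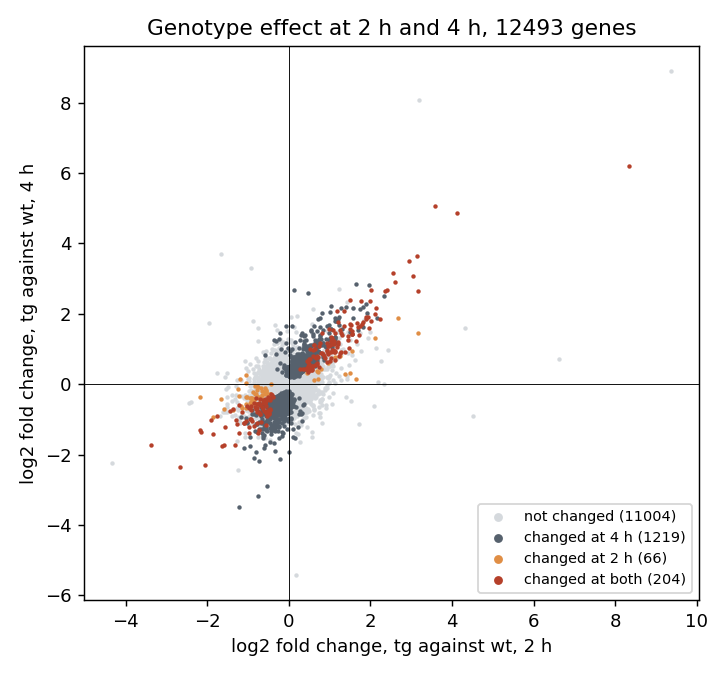
Log2 fold change of tg against wt at 2 h (x axis) and 4 h (y axis) for 12493 genes, coloured by where the gene was called. The genes called at both durations lie in the upper right or the lower left, with 0 in opposite directions.

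The difference between the effects at 4 h and 2 h was called for 0 genes by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, with 723 at an unadjusted p under 0.05, while DESeq2 called 6 and limma-voom 0. The smallest p-values were those of Osbpl11, a lipid-binding protein (difference 1.01 ± 0.20), Ifnar1, an interferon receptor subunit (-0.49 ± 0.10), Lgr5 (-1.25 ± 0.26) and Id1, an inhibitor of helix-loop-helix factors (1.31 ± 0.28), each with an adjusted p of 0.367 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Leaving out wt 4 h replicate 1 gave 3 genes.

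Within tg mice 114 genes differed between 4 h and 2 h, 33 higher and 81 lower at 4 h, by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Slc25a34 was higher at 4 h by 1.45 ± 0.23 and Id1 by 1.17 ± 0.21, while Lgr5 (-1.43 ± 0.19), Nr3c2, the mineralocorticoid receptor (-1.42 ± 0.24), and Klhdc7a (-1.53 ± 0.26) were lower. The count fell to 20 without tg 2 h replicate 3, 55 without tg 2 h replicate 5, 35 without tg 4 h replicate 1, 41 without tg 4 h replicate 4 and 25 without tg 4 h replicate 5. Within wt mice 0 genes differed by the same test, 747 had an unadjusted p under 0.05, and DESeq2 called 1 and limma-voom 0. Bcl6, a transcriptional repressor, had the smallest of these p-values with a change of -1.93 ± 0.38 and an adjusted p of 0.821 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, or 0.0301 without wt 4 h replicate 1. Start of light and duration of food absence also differed between durations, since all livers were taken at the same time of day.

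The authors' deposited table called 523 genes at 2 h and 1605 at 4 h. Of the 270 and 1423 genes called here, 267 and 1324 were also called in the authors' deposited table, none with the opposite sign.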

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

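Most tests here were chosen after the result was seen, namely those of fewer tg libraries, of labels, of mixed RNA, of transcript length, of hepatocyte share and of other splits, while those of standard errors, of larger changes and of title numbers were planned. The limit for the label exchange was changed, and the macrophage and urea cycle lists chosen, after the values they decide on were known.

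In 39 of 448 groups of libraries 1 library lay far from the others of its group, where the limit used marks about 1 in 20 groups of independent values by chance. The groups share libraries, with 12 of the 39 in tg 4 h replicate 3, and no chance rate was computed for them. In tg 4 h replicate 3 the CPM values were 3.86 for Fam107a (others 37.5 to 46.9), 137 for Arrdc3 (11.5 to 34.3), 2398 for Tat (4508 to 5199), 3447 for Pck1 (5056 to 5332), 130 for Slc38a2 (374 to 420), 20.4 for Irf1 (8.25 to 10.1), 5.03 for Tfap4 (1.77 to 2.46), 3.89 for Trib3 (7.47 to 8.72), 7402 for Ass1 (4780 to 5511), 2655 for Arg1 (1736 to 1985), 19.7 for Cited2 (11.2 to 13.0) and 2.04 for Col25a1 (0.387 to 0.835). Other tg libraries far from their group were replicate 4 at 4 h for Nr4a1 (8.62 CPM), replicate 5 at 4 h for Hnf4a (951 CPM), replicate 5 at 2 h for Hnf4a (739 CPM) and Plin5 (127 CPM), replicate 3 at 2 h for Neu1 (35.9 CPM) and replicate 2 at 2 h for Arg1 (2223 CPM).

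Among wt 4 h libraries such values were 3.41 CPM for Cdkn1a, 178 for Map1lc3b, 26.7 for Acot1 and 62.0 for Id3 in replicate 5, 86.2 for Igfbp1 and 13.9 for Jun in replicate 1, 8.75 for Gadd45a and 0.507 for Ihh in replicate 4 and 2.59 for Il1b in replicate 3. Among wt 2 h libraries they were 16.3 CPM for Ddit4, 34.8 for Nr1d1 and 10.3 for Cebpd in replicate 2, 2.57 for Calhm6, 278 for Dbp, 4114 for Ass1, 25.1 for Stab1 and 12.0 for Cited2 in replicate 3, and 59.8 for Nr1i2, 586 for Hnf4a, 5.64 for Sox9 and 6.29 for Slc25a34 in replicate 4.

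The genotype effect differed between durations for 3 gene lists by camera with the preset correlation. The adjusted p was 0.00293 for the joint list of endoplasmic reticulum chaperones and the unfolded protein response (lower at 4 h), 0.00293 for urea cycle and amino acid breakdown genes (higher at 4 h) and 0.0471 for oxidative phosphorylation genes (lower at 4 h). With an estimated correlation each had an adjusted p = 0.999. Adam2, which has no row of counts, had a log2 fold change of 4.53 at 4 h in the authors' deposited table and was the 1 called gene of that table outside the counts.

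The place of tg 4 h replicate 3 between the genotypes was weighed first. Exchanging its label with wt 4 h replicate 1 gave 888 genes against 1423 as labelled. The difference of 535 (jackknife SE 201) kept its sign without each of the other 8 libraries, which argues against that exchange. Yet of 25 exchanges of 1 tg with 1 wt library at 4 h it came closest to the labels as given, the others giving at most 287 genes. The share of called genes decided nothing. It was 72.0% beyond the other 4 wt libraries on the tg side, and up to 67.8% in a wt library set against 3, an easier bar. The called urea cycle and amino acid breakdown genes lay at 1.46, with or without that wt library, while the highest position of a wt library over any list was 0.614 or 0.633 (SD 0.279 in both), so a wrong label alone would leave them unexplained, and as their lower quartile of 0.721 lay above the 0.554 of all called genes, so would mixing of RNA like that of the other tg livers with wt RNA. For the other called genes a single wrong label stays open, because 0.554 lies within 1 SD of wt replicate 1 at 0.534. In tg 4 h replicate 3 60.5% of called genes lay beyond all 5 wt libraries on the tg side. The highest share in a wt library was 64.3%, against only 4 wt libraries and over its own called genes, so these shares are not fully comparable. A weaker excitation of the neurons in that mouse may also account for the position of those other genes, and was not tested. An effect that was only weaker would likewise leave the urea cycle and amino acid breakdown genes at 1.46 unexplained.

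More genes changed at 4 h than at 2 h. Fewer tg libraries at 2 h could not account for it, since the lowest 4 h count without 1 tg library was 974. The 2 h standard errors given to the 4 h changes left 1157 genes. The model estimated the spread of a gene over all groups together. These standard errors therefore could not show a larger spread within the 2 h groups, which stays open. Larger changes after longer stimulation stay open. Over 1774 genes called for the mean effect the summed change was 1.32 times that at 2 h, with a one-sided permutation p of 0.0817. The longer absence of food and the earlier start of light go with duration and were not tested.

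An axis of expression within groups held 20.0% of the within-group variance and ran from -34.2 in wt 2 h replicate 3 to 34.0 in wt 4 h replicate 1. A lower share of hepatocytes would raise markers of all other cell types, and was argued against by the stellate (r = 0.897) and macrophage (r = 0.112, members at 4.32 to 59.5 CPM) lists, whose correlations with the axis differed by 0.785 (permutation p 0.0010). More stellate or endothelial (r = 0.796) cells stay open. So do more adipocytes or mesothelial cells, whose joint list (r = 0.781) had only 5 measured members, at 0.426 to 5.90 CPM. The neutrophil list, tried first, lay at 0.185 to 1.49 CPM, too low to decide. Lists other than cell markers followed the axis about as strongly, among them hormone and transmitter receptors (r = 0.850), glycogen and glycolysis genes (0.803) and insulin-repressed FoxO targets (0.798). Ribosomal protein genes ran the other way (r = -0.755), and hepatocyte markers had an r of -0.256. The cause of these correlations was not tested. Transcript length is a candidate explanation, with a Spearman's rho of 0.502 across 12493 genes, which are not independent replicates, between length and weight on the axis. Runs of title numbers held 34.9% of the axis variance (permutation p 0.0951, median of permutations 15.3%), which leaves them open, and no group of the design could be tested as a biological explanation, because the axis lies within groups.

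Other splits of the libraries were drawn 100 times per comparison, the real split included. At 2 h 3 splits gave as many genes as the real 270, the real one included, and the others gave 707 and 520. That points to a structure of the samples across genotype. The share of 3 in 100 is under 0.05, a limit set after the result was seen. As mixed splits gave more genes than the real one, the count at 2 h alone does not separate genotype from that structure. At 4 h 1 split, the real one with 1423, gave as many (highest other drawn 287). The exchange of tg 4 h replicate 3 with wt 4 h replicate 1, a possible split that was not drawn, gave 888. Only the real split gave as many for the mean effect too (1 split, 1774 against 394) and for tg between durations (1 split, 114 against 26). In these comparisons chance is made unlikely, but it cannot be excluded, because 1 in 100 is the smallest share that these draws can give. For the difference between durations and for wt between durations the real count was 0, which all 100 splits must reach, so splits decide nothing there. The highest other counts were 20 and 505, the latter again pointing to a structure of the samples.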

How the results depend on the processing

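The alternatives were planned, except DESeq2 on only the groups compared the removal of glucocorticoid targets from the other lists and list calls without each library, which were chosen after seeing the data. Under DESeq2 the counts were 425 at 2 h, 6 for the difference between durations, 1 for wt and 289 for tg between durations, and 533 at 2 h with only the groups compared. Sample quality weights in limma-voom gave 2286 genes at 4 h, 1 in wt and 208 in tg between durations, and an adjusted p under 0.10 gave 238 in tg. Lists called with an estimated correlation numbered 2 at 2 h and 2 at 4 h against 11 and 7, and fry called 3 at 2 h and 6 at 4 h. The correlation of fold changes was 0.422 without a filter on low counts, 0.702 with a mean of at least 50, 0.554 with the run of title numbers as a covariate and 0.507 as Spearman's rho. For these values the cause was not tested, except that a wider threshold admits more genes. With 1 library left out the counts ran from 151 to 244 at 2 h, 895 to 1887 at 4 h, 0 to 3 for the difference, 1405 to 2113 for the mean effect, 0 to 1 in wt and 20 to 134 in tg, the lists from 8 to 12 and 6 to 10, and the correlation from 0.535 to 0.631. Jchain, not called, ran from -0.19 (without tg 4 h replicate 4) to 0.90 at 4 h. Of the named genes called, 20 of 47 at 2 h, 22 of 84 at 4 h and 5 of 10 in tg lost the call in at least 1 such fit. None of them reversed. Without glucocorticoid targets in the other lists, 8 lists at 2 h and 5 at 4 h were called.

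Replicate numbers showed no clear pairing of tg with wt mice within a duration. Same-numbered tg and wt libraries of a duration had a mean correlation of -0.0298 (-0.329 to 0.186), and 4 of 9 pairs were over 0.1. Over all groups 27 pairs shared a number (mean correlation 0.0138) and 108 did not (-0.00344). There 8 of 19 libraries matched their own number best, which is above an even share, so a link by number is not excluded. With the replicate block the counts were 276 at 2 h, 1427 at 4 h, 0 for the difference, 1750 for the mean effect, 0 in wt and 78 in tg. Of the genes called without the block 230 at 2 h, 1288 at 4 h and 64 of 114 in tg were shared. With the run of title numbers as a covariate the counts were 261 at 2 h, 1155 at 4 h, 1490 for the mean effect and 134 in tg. Of the genes called without it 208, 1051, 1351 and 91 were shared. The tg 4 h libraries lay in runs 1 to 3 and the wt 4 h libraries in runs 2 to 4. Upper-quartile scaling gave 608 higher and 828 lower genes at 4 h, and 751 higher and 1062 lower for the mean effect. At these depths a 1.5-fold change was recovered in 46.3% of simulated cases at 2 h, so small changes were often missed.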

Other observations

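The gene lists of this part were fixed with the others, and no test was added for them. Glycogen and glycolysis genes rose in 3 of 18 cases at 4 h, or 5 adjusted over the list alone, and the list was not shifted by camera (adjusted p = 0.107). Ppp1r3b and Ppp1r3c, which target protein phosphatase 1 to glycogen, rose by 2.17 ± 0.42 and 2.28 ± 0.50 (log2, SE, n = 5 mice per genotype). Of 24 cholesterol genes 1 rose and 1 fell (adjusted p of the list by camera 0.854), and Stard4, a sterol carrier, was the one that fell, by 0.66 on the log2 scale.

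Genes of the integrated stress response and amino acid synthesis rose in 3 and fell in 1 of 18 cases at 4 h, with the same counts adjusted over the list alone and a camera adjusted p = 0.107. Sesn2, a leucine sensor upstream of mTORC1, rose by 0.77 ± 0.14, while Trib3, a pseudokinase of the stress response, changed by -1.38 ± 0.31. Cebpa, a hepatocyte transcription factor, fell by 0.59 on the log2 scale at 2 h and by 0.52 at 4 h.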
